A study of Homo sapiens with 10 samples.

How the data were processed

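The series holds 10 poly(A) RNA-seq libraries of skin fibroblasts grown from 5 donors with scleroderma, 1 control and 1 LiCl library per donor. Per the labels' protocols, the cells were grown in 10% serum, starved for 12 h in 1% serum and treated for 24 h. The authors deposited 1 table of gene-level expected counts, which RSEM estimates by sharing reads among transcripts. Per the submitters' processing notes the tools were cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a and RSEM 1.3.3, with the genome build GRCh38. The annotation release and the strand setting of the counting are not given in the sources used here, so counts of genes that overlap on opposite strands are uncertain, as are those of near-identical paralogs. The expected counts were rounded to whole numbers for the tests, although 0 of the deposited values were not whole. The table has 61546 genes, 40844 of them with a symbol, and 61369 of its Ensembl IDs were found in a table of gene names. Coordinates come from GENCODE release 29 on GRCh38 and were joined by gene ID. Library totals were 23707643 to 40376641 counts, and no library was a duplicate of another.

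Each column was matched to a sample through its label, and the donor and treatment come from the sample titles. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15835 genes and at least 99.9% of the counts of each library. Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F-test, robust dispersions) in R 4.3.3, with donor as a block plus treatment, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are LiCl over control, and the standard error of a log2 fold change is its size divided by the square root of F. Levels are TMM-scaled CPM (counts scaled to a fixed library total), and log2 CPM used a prior count of 2. The biological coefficient of variation was 21.1%. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 5 members were tested, and again with a correlation estimated for each list and with fry. The directional p of fry asks whether a list's genes move on balance in the same direction, without comparing it with other genes. Ratios of genes with 1 to 3 counts in a group carry a 95% counting interval. Exact paired permutation tests are two-sided.

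The titles name the donor of each library, so the 2 libraries with the same number come from the same donor. After the group means were removed, the 2 libraries of a donor correlated at 0.506 to 0.608, and each library pair correlated best with its own number. The model therefore holds the donor as a replicate block, and the fit with no replicate block, which called 9482 genes, is among the alternatives.

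The named genes, the lists, the tests and most alternatives were chosen before the data were examined. The rule for named genes took the 12 with the largest rise and the 12 with the largest fall among 8688 genes with an adjusted p under 0.05, the same direction in all 5 donors, a mean of at least 1 CPM and a symbol, leaving out genes that could tell the sex of a donor. It added 21 genes fixed by name. Those reported here were COL1A1, COL1A2, COL3A1, FN1, ACTA2, TAGLN, CCN2, POSTN, AXIN2, LEF1, NKD1, GSK3A, GSK3B, CTNNB1, IMPA1, IMPA2, GLI1, PTCH1, IL6 and MKI67. Added to these were up to 4 members with the smallest p of each list, and up to 6 of a list past the camera threshold. Other genes are said to have been named after their values were seen, except the families of the closing part and the members of marker lists.

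The 37 lists were as follows. Lists of signalling were Wnt/beta-catenin targets, secreted Wnt antagonists, TGF-beta response, BMP pathway, YAP/TAZ targets, Hedgehog pathway and cAMP response. Lists of the matrix and contractile cells were collagens, non-collagen matrix proteins, collagen processing and cross-linking, contractile and myofibroblast genes, and matrix proteases and inhibitors. Inflammatory cytokine and NF-kB genes and interferon response were lists as well. Ciliary transport, cilium disassembly, mitosis, DNA replication, p53 targets and circadian clock made further lists. Stress lists were NRF2 targets, endoplasmic reticulum chaperones and unfolded protein response, ATF4 targets and amino acid genes, osmotic stress, heat shock, metallothioneins, immediate early genes, and lysosome and autophagy. Lists of metabolism were cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, inositol and lithium-sensitive phosphatases, adipogenic and lipid storage genes, and glycogen metabolism. The last were nuclear oxidative phosphorylation, mitochondrially encoded mRNAs and cytosolic ribosomal proteins. A further 9 lists held markers of fibroblasts, keratinocytes, endothelial cells, leukocytes, pericytes and smooth muscle, melanocytes, Schwann cells and adipocytes, and genes used to judge RNA quality. Counts over a list are over all genes tested, and those adjusted over the list alone are given where they differ and were otherwise equal.

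The alternatives were RLE and upper-quartile scaling, no filter, a stricter filter (1 CPM in at least 5 libraries), DESeq2 1.42.0, limma-voom, no replicate block, non-robust dispersions, thresholds of 0.01 and 0.10, other prior counts (0.5 and 5), and leaving out both libraries of each donor in turn. The order of the libraries in the set tests was added after the data were seen. The scripts were tested on simulated counts for this comparison, drawn for 15835 genes with 200 changed, of which 15629 genes passed the filter. In that test edgeR recovered 29.9% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 90.9% of those changed 4-fold, and 16 of its 144 calls (11.1%) were genes left unchanged, a share above the nominal threshold of 0.05. DESeq2 recovered 46.3%, 79.1% and 92.4% with 24.9% of its calls unchanged, limma-voom 25.4%, 74.6% and 92.4% with 10.5%, and edgeR with no replicate block 2.99%, 29.9% and 71.2% with 0 of 69. In the real data a far larger share of the tested genes was called (67.2%), so these recovery and error shares need not carry over. Camera called 0 of 30 random lists in the simulated data. The genes were drawn independently of one another there, so this count does not test the preset correlation of 0.01.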

Results

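Poly(A)-selected RNA was sequenced from skin fibroblasts grown from 5 donors with scleroderma (systemic sclerosis), a disease in which the skin scars and hardens. Each donor gave 1 control library and 1 library of cells kept with lithium chloride (LiCl) for 24 h after 12 h in 1% serum, so that 5 control libraries were compared with 5 LiCl libraries. Lithium is known to inhibit glycogen synthase kinase 3 (GSK3), which marks beta-catenin for destruction, and inositol monophosphatase, which recycles inositol. The dose of LiCl and what the control cultures received in its place are not given in the sources used here, so an effect of lithium cannot be separated from an effect of the added salt. Library totals ran from 23707643 to 40376641 counts. Their mean was 35817000 ± 4363600 in control and 31962000 ± 5359500 in LiCl libraries (SD, n = 5 each, exact two-sided paired permutation p = 0.1875, LiCl higher in 1 of 5 donors). With 5 donors the smallest p such an exact paired test can give is 0.0625.

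The comparison asked which genes scleroderma fibroblasts expressed at another level after LiCl. The chief fibrillar collagen genes of skin, COL1A1, COL1A2 and COL3A1, fell, with COL1A1 3.02-fold lower (6012 ± 2181 CPM in control and 2092 ± 1084 CPM in LiCl libraries, SD, n = 5). Of the tested members of each list, 17 of 21 interferon response genes fell, among them IFIT1 (19.1-fold lower), 16 of 23 cholesterol synthesis genes, among them LSS (4.26-fold lower), and 9 of 10 Hedgehog pathway genes, among them GAS1 (8.21-fold lower). There were rises in 14 of 22 DNA replication genes, among them CDC6 (7.69-fold higher), 9 of 12 heat shock genes, among them HSPD1 (2.90-fold higher), and 11 of 15 immediate early genes, among them FOSL1 (6.60-fold higher). Camera with its preset correlation called each of these lists, and none held (adjusted p = 0.768 for each) with an estimated correlation. Each of the genes named here moved the same way in all 5 donors. Of 15835 genes tested, 10641 (67.2%) changed at an edgeR adjusted p under 0.05, 5106 of them higher and 5535 lower, and 5488 changed at least 2-fold (2264 higher, 3224 lower). The direction was the same in all 5 donors for 10021 of the changed genes (94.2%).

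Among the genes that rose most, TPPP3 and TPPP, which promote tubulin polymerization, rose by 9.70 ± 0.65 and 9.11 ± 0.52 on the log2 scale (SE, edgeR adjusted p = 2.71e-05 for TPPP3). TPPP3 went from 0.739 ± 0.50 to 677 ± 366 CPM (SD, n = 5). NOTUM, which inactivates secreted Wnt proteins, rose from 0.278 ± 0.120 to 33.5 ± 16.0 CPM (log2 fold change 6.78 ± 0.33). The neuropeptide gene CCK (7.89 ± 0.82), the keratin gene KRT16 (7.25 ± 0.58), the doublecortin-domain gene DCDC2C (7.19 ± 0.56), the axonemal gene TTC29 (6.93 ± 0.44), the calcineurin-regulated factor NFATC2 (6.93 ± 0.43) and the presynaptic scaffold PCLO (6.84 ± 0.28) rose as well. Control means were near 0 for KRT16 (0.0258 CPM), CCK (0.0323 CPM), TTC29 (0.0499 CPM), DCDC2C (0.0914 CPM) and TPPP (0.116 CPM), so the sizes of their rises are uncertain. Control counts were still lower in 3 further genes, too low for a stable fold change. The chemokine gene CCL18 had 1 count in the 5 control libraries together and 1676 in the LiCl libraries, a depth-adjusted ratio of 1854 (95% counting interval 332 to 73263). LINC02725 had 1 and 448 counts (ratio 496, interval 88.5 to 19615), and the noradrenaline transporter gene SLC6A2 had 2 and 553 (ratio 306, interval 84.3 to 2532). The SLC6A2 ratio leans on 1 LiCl library, since without replicate 5 it had 2 and 198 counts (ratio 101, interval 27.5 to 837), and without replicate 3 the LINC02725 ratio was 328 (interval 58.5 to 13016). The control counts of each of the 3 genes came from a single library. Without that library's donor, and with the control at a floor of 3 counts over the group, CCL18 was at least 460.2-fold higher, LINC02725 at least 151-fold and SLC6A2 at least 197-fold. These intervals cover counting error only.

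Among the genes that fell most, GBP4 (log2 fold change -5.57 ± 0.45 SE), IFIT2 (-4.65 ± 0.59) and TNFSF10, which encodes the death ligand TRAIL (-4.80 ± 0.53), are interferon-induced. The control level of GBP4 ran from 0.0261 CPM in replicate 5 to 103 CPM in replicate 3. Its LiCl minus control difference ran from -6.57 to -0.53 log2 CPM between donors, so the size of its fall is uneven. FRAT1, whose protein binds GSK3 and keeps it from beta-catenin, fell from 5.23 ± 1.92 to 0.160 ± 0.159 CPM (SD, n = 5, log2 fold change -4.94 ± 0.51). The vitamin D 24-hydroxylase gene CYP24A1 (-5.05 ± 0.47), the activin subunit gene INHBB (-4.69 ± 0.27) and the matrix metalloprotease gene MMP11 (-4.61 ± 0.42) fell, as did LCNL1 (-4.91 ± 0.47), OSBPL7 (-4.68 ± 0.47), YPEL4 (-4.65 ± 0.58) and STON1-GTF2A1L (-4.74 ± 0.84). STON1-GTF2A1L is a readthrough gene that shares exons with its neighbours, so its count is uncertain. C10orf105 had 438 counts in control and 2 in LiCl libraries, a ratio of 198 (95% counting interval 54.5 to 1640), and of 351 without replicate 3 (interval 62.6 to 13880).

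In the annotation of GRCh38 used here, COL1A1 (ENSG00000108821) lies on chromosome 17 from 50183289 to 50201632, COL1A2 (ENSG00000164692) on chromosome 7 from 94394561 to 94431232 and COL3A1 (ENSG00000168542) on chromosome 2 from 188974320 to 189012746. ACTA2 (ENSG00000107796) lies on chromosome 10 from 88935074 to 88991339 and AXIN2 (ENSG00000168646) on chromosome 17 from 65528563 to 65561647. TPPP3 (ENSG00000159713) lies on chromosome 16 from 67389809 to 67393535, NOTUM (ENSG00000185269) on chromosome 17 from 81952507 to 81961840, CCL18 (ENSG00000275385) on chromosome 17 from 36064280 to 36072032 and IFIT2 (ENSG00000119922) on chromosome 10 from 89283694 to 89309276. All 9 are protein-coding genes, and their values sum the exons of the whole gene.

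**Figure D1:**
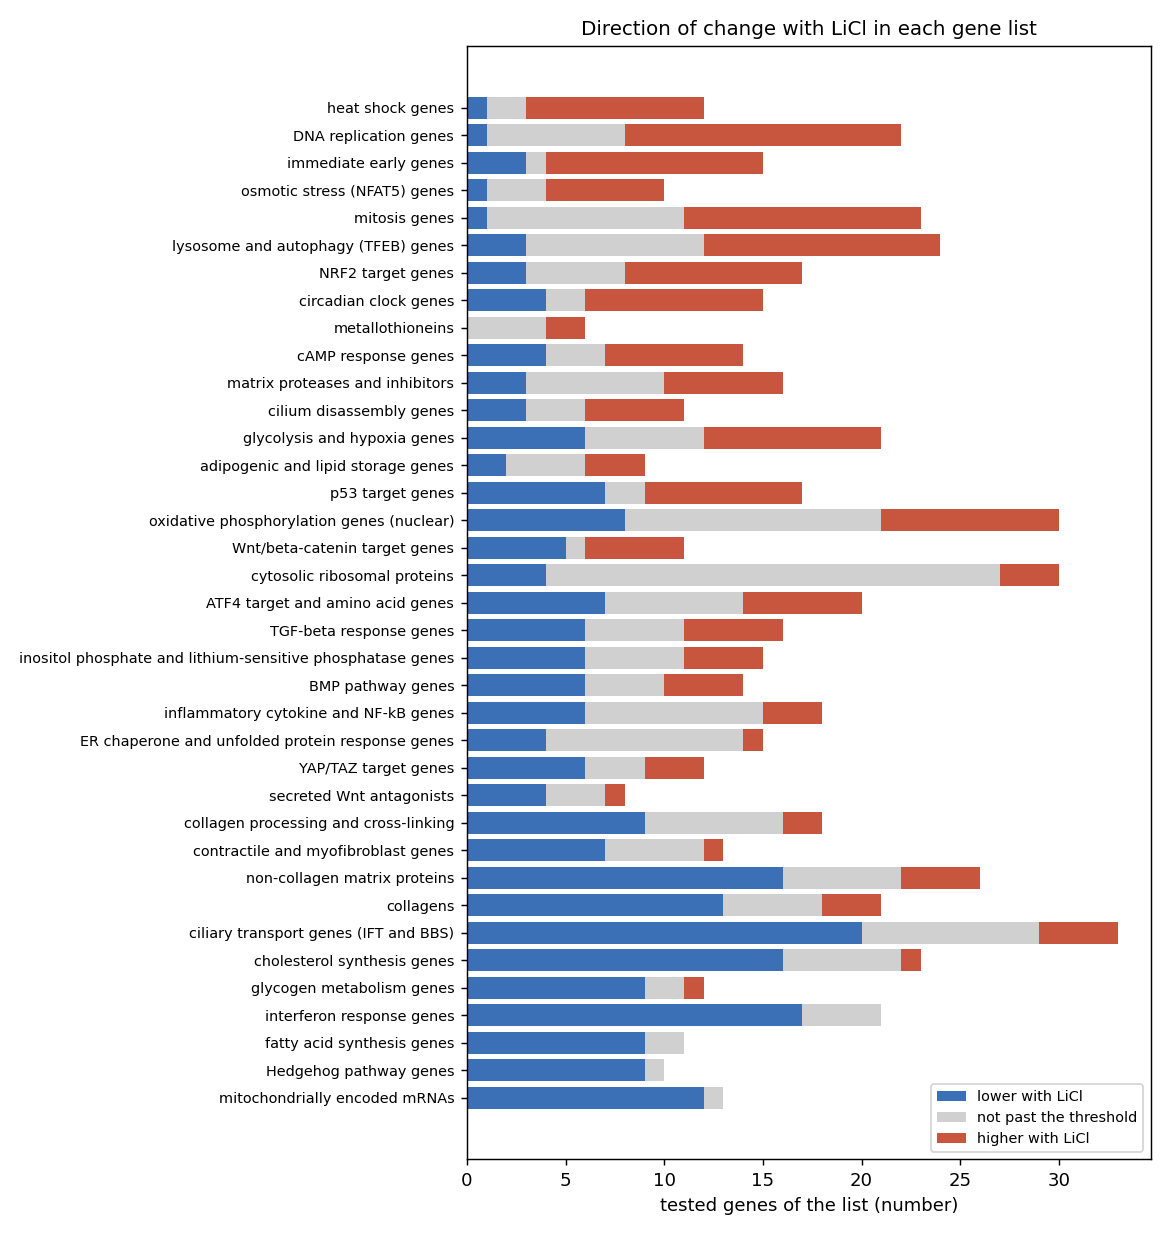
Horizontal bars count the tested members of each of the 37 gene lists (x axis, number of genes) that were lower, not past the threshold or higher with LiCl (edgeR adjusted p under 0.05 over all genes tested). The Hedgehog bar holds 9 lower genes and 1 not past, and the DNA replication bar 14 higher, 1 lower and 7 not past.

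Collagen genes fell more often than they rose: 13 of 21 were lower with LiCl, 3 were higher and 5 did not pass the test. COL1A1 (log2 fold change -1.59 ± 0.14 SE, edgeR adjusted p = 2.28e-05), COL1A2 (-0.97 ± 0.16), COL3A1 (-1.55 ± 0.34), COL5A2 (-1.19 ± 0.12) and COL6A3 (-1.18 ± 0.12) fell in all 5 donors. The growth plate collagen gene COL10A1 (1.39 ± 0.25), the basement membrane gene COL4A1 (0.67 ± 0.12) and COL5A3 (0.31 ± 0.11) rose, all 3 named after their values were seen. COL5A3 was not past the threshold without replicate 1 (adjusted p = 0.0645), 3 (0.0631), 4 (0.0867) or 5 (0.132). Nor was it with upper-quartile scaling (0.117) or without the donor block (0.387), in a range of 0.0195 to 0.387. For the list, camera gave an adjusted p of 0.0318, with adjusted p = 0.768 with an estimated correlation, 0.0564 without replicate 1 and 0.11 without the replicate block. Fibroblast markers moved with the collagens, since 7 of 8 fell, among them the 2 type I collagen genes and PDGFRA (-1.29 ± 0.21), while VIM stood at -0.27 ± 0.21 (adjusted p = 0.276, and 0.0189 without replicate 3, in a range of 0.0189 to 0.590).

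Of 26 non-collagen matrix genes, 16 fell, 4 rose and 6 did not pass (5 higher and 16 lower adjusted over the list alone). Thrombospondin 1 (THBS1) fell from 5.64e+03 to 382 CPM (log2 fold change -3.87 ± 0.15 SE, edgeR adjusted p = 1.73e-06), and fibrillin 1 (FBN1, -1.60 ± 0.16) and fibronectin (FN1, -0.72 ± 0.14) fell. Tenascin C (TNC) rose by 2.04 ± 0.24. Periostin (POSTN) rose by 0.55 ± 0.18 in 4 of 5 donors (adjusted p = 0.0202), a call that ended without replicate 2 (0.0530), 4 (0.0672) or 5 (0.0758) and without the donor block (0.321), in a range of 0.00334 to 0.321. The camera adjusted p was 0.0588 for this list, and fell under the threshold without replicate 4 (0.0429) or 5 (0.0425), in a range of 0.0425 to 0.768. The fry adjusted p was 0.0106. Among 18 collagen processing and cross-linking genes 9 fell, 2 rose and 7 did not pass (camera adjusted p = 0.104, and 0.0467 without replicate 4, in a range of 0.0467 to 0.768, with a fry adjusted p of 0.0176). The lysyl oxidase-like genes LOXL4 (-3.15 ± 0.15), LOXL1 (-2.11 ± 0.19) and LOXL3 (-2.01 ± 0.24) fell, and the lysyl hydroxylase genes PLOD2 (1.66 ± 0.21) and PLOD3 (0.61 ± 0.09, named after its value was seen) rose.

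Of 13 contractile and myofibroblast genes, 7 fell, 1 rose (2 with RLE or library-size scaling) and 5 did not pass (camera adjusted p = 0.125). Smooth muscle actin (ACTA2, -0.95 ± 0.20, edgeR adjusted p = 0.00268), tropomyosin (TPM2, -1.35 ± 0.11), caldesmon (CALD1, -1.21 ± 0.11) and myosin light chain (MYL9, -1.16 ± 0.12) fell in all 5 donors. MYH11, named after its value was seen, rose by 1.55 ± 0.30 from 0.313 CPM. TAGLN stood at 0.19 ± 0.26 (adjusted p = 0.550, higher in 2 of 5 donors). Genes that respond to transforming growth factor beta were divided, 5 higher, 6 lower and 5 not past of 16 (camera adjusted p = 0.896). CCN2 (0.85 ± 0.14) rose in all 5 donors, and TGFB1 (-0.63 ± 0.09), TSC22D1 (-0.74 ± 0.10) and the cell cycle inhibitor gene CDKN2B (-1.33 ± 0.21) fell. Of 14 bone morphogenetic protein pathway genes, 4 rose, 6 fell and 4 did not pass (camera adjusted p = 0.402), with BMP2 higher by 2.49 ± 0.25 and the inhibitors SMAD6 (-4.07 ± 0.26) and FST (-2.29 ± 0.15) lower.

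Of 16 matrix protease and inhibitor genes, 6 rose, 3 fell and 7 did not pass (5 higher and 5 lower with upper-quartile scaling, camera adjusted p = 0.329). ADAMTS1 rose by 3.57 ± 0.33 on the log2 scale (SE, edgeR adjusted p = 5.56e-05), MMP16 by 1.58 ± 0.17, the interstitial collagenase gene MMP1 by 1.29 ± 0.13 and the stromelysin gene MMP3, named after its value was seen, by 3.52 ± 0.69. Without the donor block the call of MMP1 ended (adjusted p = 0.0768, in a range of 8.07e-27 to 0.0768). MMP1 and MMP3 together took 0.727 ± 0.473% of all counts in control and 2.60 ± 1.20% in LiCl libraries (SD, n = 5, exact paired p = 0.0625, higher in 5 of 5 donors). Of 18 inflammatory cytokine and NF-kB genes, 3 rose, 6 fell and 9 did not pass (camera adjusted p = 0.249). VCAM1 (-4.52 ± 0.43), CXCL12 (-2.03 ± 0.21) and IL6 (-2.79 ± 0.50) fell, and PTGS2 (2.65 ± 0.48), IL33 (2.59 ± 0.60) and TNFAIP6 (1.84 ± 0.55), named after their values were seen, rose. Without the donor block the calls of IL6 (adjusted p = 0.11, range 3.90e-07 to 0.11), PTGS2 (0.0658, range 1.46e-06 to 0.0658) and TNFAIP6 (0.280, range 0.00238 to 0.280) ended. TNFAIP6 was also not past the threshold without replicate 1 (0.0517) or 4 (0.0566) or with no filter (0.124), nor was IL33 with no filter (0.0571, range 1.41e-08 to 0.0571). Of 12 YAP/TAZ target genes, 3 rose, 6 fell and 3 did not pass (camera adjusted p = 0.329). F3 (1.69 ± 0.13), CCN2 and ANKRD1 (2.37 ± 0.40, named after its value was seen) rose, and AJUBA (-1.88 ± 0.24) and NT5E (-1.32 ± 0.16) fell.

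Interferon response genes fell: 17 of 21 were lower, none was higher and 4 did not pass with edgeR over all genes tested. Adjusted over the list alone, 17 were lower and 2 higher, and 2 were also higher at an unadjusted p under 0.05, with DESeq2, with limma-voom and with upper-quartile or library-size scaling. IFIT1 fell from 377 to 10.0 CPM (log2 fold change -4.26 ± 0.47 SE, edgeR adjusted p = 2.14e-04), and MX2 (-3.78 ± 0.45), OAS2 (-3.62 ± 0.46), the interferon regulator IRF7 (-3.39 ± 0.38) and XAF1 (-3.31 ± 0.34) fell in all 5 donors. RSAD2 and CMPK2, neighbouring genes named after their values were seen, went the other way, at 3.21 ± 1.20 (adjusted p = 0.0503, higher in 5 of 5 donors) and 2.51 ± 0.97 (0.0555, higher in 4 of 5). Without replicate 3 both passed (adjusted p = 0.0145 for RSAD2, range 0.00158 to 0.601, and 0.00828 for CMPK2, range 0.00495 to 0.627). The camera adjusted p for the list was 2.95e-04, with adjusted p = 0.768 with an estimated correlation and 0.220 without the replicate block. The median difference over the list ranged from -4.72 in replicate 3 to -1.23 in replicate 5. Of the leukocyte markers, 0 of the 4 tested passed with edgeR or limma-voom, 1 passed with DESeq2 and 1 had an unadjusted p under 0.05 with edgeR. PTPRC, CD3E, LYZ and MS4A1 had means of at most 0.0672 CPM in both groups.

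Hedgehog pathway genes fell, 9 of 10 lower and 1 not past with edgeR, DESeq2 and limma-voom alike. The receptor gene PTCH1 (log2 fold change -2.25 ± 0.24 SE, edgeR adjusted p = 5.97e-05), the transducer SMO (-3.75 ± 0.27), the coreceptors BOC (-1.85 ± 0.12) and GAS1 (-3.04 ± 0.29) and the inhibitor SUFU (-1.18 ± 0.14) all fell in 5 of 5 donors. The list gave a camera adjusted p of 0.00154, and adjusted p = 0.768 with an estimated correlation. GLI1, a target of the pathway, had 9 counts in control and 19 in LiCl libraries and was not tested (log2 fold change 0.81 ± 1.00, adjusted p = 0.617 with no filter). The list member HHIP, also not tested, went the other way from the list, with 8 and 76 counts (0.0417 ± 0.0453 and 0.395 ± 0.590 CPM, SD). Ciliary transport genes were lower in 20 of 33 cases, higher in 4 and not past in 9 (camera adjusted p = 0.00979, and adjusted p = 0.768 with an estimated correlation). IFT140 (-2.41 ± 0.13), IFT122 (-2.14 ± 0.22), the dynein gene DYNC2H1 (-1.88 ± 0.14) and BBS1 (-1.78 ± 0.13) fell. The list members BBS5 (0.90 ± 0.12), WDR35 (0.90 ± 0.22) and BBS7 (0.59 ± 0.14), named after their values were seen, were among those that rose. Of 11 cilium disassembly genes, 5 rose, 3 fell and 3 did not pass (camera adjusted p = 0.471), with PIFO at 2.53 ± 0.17, AURKA at 1.26 ± 0.20, NEDD9 at -3.14 ± 0.30 and HDAC6 at -2.07 ± 0.24.

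Components and targets of the Wnt pathway moved both ways. Of 11 tested members of the beta-catenin target list 5 rose, 5 fell and 1 did not pass. NOTUM rose, and AXIN2 rose by 1.42 ± 0.46 on the log2 scale in 4 of 5 donors (SE, edgeR adjusted p = 0.0296). TCF7 (3.67 ± 0.60), CCND1 (0.97 ± 0.16) and ZNRF3 (0.95 ± 0.18), named after their values were seen, rose in 5 of 5 donors. Of the list's other members, APCDD1 (-3.33 ± 0.22), TCF7L2 (-1.51 ± 0.14), which encodes a transcription factor of the pathway, and PORCN (-1.07 ± 0.14), whose enzyme acylates Wnt proteins for secretion, fell. MYC (-0.91 ± 0.13) and LGR5 (-2.03 ± 0.36), named after their values were seen, fell as well. The call of AXIN2 ended without replicate 2 (adjusted p = 0.0826), 4 (0.0706) or 5 (0.0552) and with no filter (0.152), in a range of 7.66e-04 to 0.152. The transcription factor gene LEF1, left out by the filter, had 8 counts in control and 217 in LiCl libraries (log2 fold change 4.91 ± 0.54, adjusted p = 3.55e-08 with no filter), and NKD1 had 16 and 64 (2.11 ± 0.67, adjusted p = 0.0167 with no filter). The list members SP5 (36 and 3 counts) and NKD2 (61 and 34), also left out, had fewer counts with LiCl, and RNF43 had 0 in both groups. For the list, the median (0.30) and the mean (0.48) lay above 0 while camera's direction was down (adjusted p = 0.957). The direction of fry was also down, with a fry adjusted p of 0.0437. The camera direction turned up without replicate 1 (adjusted p = 0.643) or 4 (0.960) and without the replicate block (0.933). Of 8 tested members of the secreted Wnt antagonist list, 4 fell, 1 rose and 3 did not pass (camera adjusted p = 0.254). DKK2 (-3.14 ± 0.16) and SFRP1 (-1.30 ± 0.18) were lower and DKK1 (1.05 ± 0.11) higher. KREMEN1 (-1.95 ± 0.15), a member that encodes a membrane receptor and not a secreted protein, was lower as well. The kinase genes GSK3A (0.67 ± 0.09) and GSK3B (0.83 ± 0.11) rose and CTNNB1, which encodes beta-catenin, fell by 0.36 ± 0.09.

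Inositol and lithium-sensitive phosphatase genes were divided, with 4 of 15 higher, 6 lower and 5 not past. IMPA1 (log2 fold change 1.51 ± 0.11 SE, edgeR adjusted p = 9.14e-06) and INPP1 (1.19 ± 0.09), whose products lithium inhibits, and the kinase gene ITPKA (3.52 ± 0.23) rose, and CDIPT, which makes phosphatidylinositol, fell by 0.75 ± 0.08. IMPA2 stood at -0.37 ± 0.18 (adjusted p = 0.0917), and passed without replicate 2 (0.0496) and with upper-quartile scaling (0.0471), in a range of 0.0471 to 0.326. The list's median (-0.24) and camera's direction lay below 0 and its mean (0.17) above (camera adjusted p = 0.896). Of 10 osmotic stress genes, 6 rose, 1 fell and 3 did not pass (camera adjusted p = 0.0618, and 0.0401 without replicate 1 or 0.0253 without replicate 2, in a range of 0.0253 to 0.768, with a fry adjusted p of 0.0118). An osmotic effect of the salt and an effect of lithium were not separated here. The water channel gene AQP1 rose by 5.23 ± 0.51, the kinase gene SGK1 by 1.46 ± 0.22 and the taurine transporter gene SLC6A6 by 0.79 ± 0.18. NFAT5 itself, named after its value was seen, fell by 0.24 ± 0.09 (adjusted p = 0.0374), a call that ended without replicate 1 (0.0716), 2 (0.178), 3 (0.111) or 5 (0.0522), in a range of 0.00766 to 0.191. Of 12 glycogen metabolism genes, 9 fell, 1 rose and 2 did not pass (camera adjusted p = 0.0588, and 0.0355 without replicate 2 or 0.0409 without the replicate block, in a range of 0.0355 to 0.768, with a fry adjusted p of 0.00346). Glycogen phosphorylase (PYGL, -2.29 ± 0.13), PPP1R3B (-1.17 ± 0.17) and UGP2 (-0.75 ± 0.10) fell and STBD1 (1.41 ± 0.16) rose.

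DNA replication genes rose, 14 of 22 higher, 1 lower and 7 not past (camera adjusted p = 5.32e-04, and adjusted p = 0.768 with an estimated correlation). The licensing factor gene CDC6 rose from 5.29 to 41.1 CPM (log2 fold change 2.94 ± 0.12 SE, edgeR adjusted p = 1.73e-06), and MCM10 (3.13 ± 0.23), GINS1 (2.46 ± 0.22), the flap endonuclease gene FEN1 (1.89 ± 0.14) and MCM3 (1.47 ± 0.10) rose in 5 of 5 donors. MCM6, which encodes a subunit of the same helicase as MCM3, fell by 1.32 ± 0.12 in 5 of 5 donors and was named after its value was seen. Of 23 mitosis genes, 12 rose, 1 fell and 10 did not pass (camera adjusted p = 0.0176, and adjusted p = 0.768 with an estimated correlation or 0.0599 without replicate 4). UBE2C (2.03 ± 0.26), CDC20 (1.84 ± 0.27) and cyclin B1 (CCNB1, 1.34 ± 0.21) rose. The proliferation marker MKI67 stood at 0.08 ± 0.24 (adjusted p = 0.780). KIF20A, named after its value was seen, fell by 0.98 ± 0.30, a call that ended without replicate 1 (adjusted p = 0.0546) and without the donor block (0.148), in a range of 0.00350 to 0.148. Of 17 p53 target genes, 8 rose, 7 fell and 2 did not pass (camera adjusted p = 0.615), with AEN (1.28 ± 0.09) and the DNA repair gene XPC (1.48 ± 0.11) higher and DDB2 (-1.33 ± 0.13) lower.

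**Figure D2:**
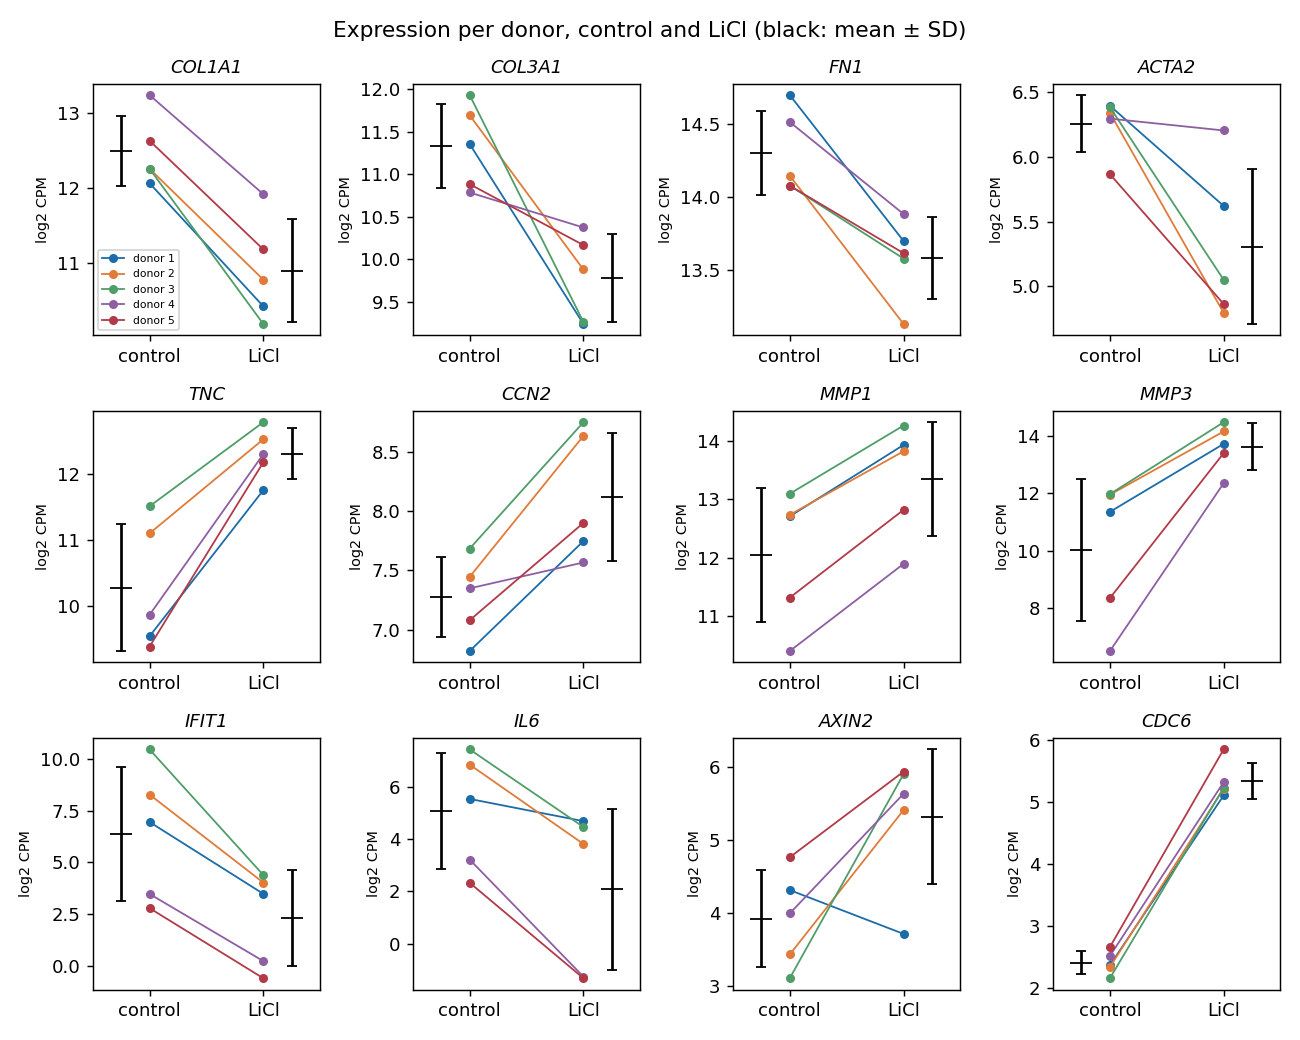
Points show log2 CPM (y axis) of 12 genes in the control and LiCl libraries, with a line joining the 2 libraries of each donor and black marks for the mean ± SD (n = 5). COL1A1, COL3A1, IFIT1 and IL6 go down in all 5 donors, CDC6, TNC and CCN2 go up in all 5, and AXIN2 goes up in 4.

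Enzymes of lipid synthesis fell. Of 23 cholesterol synthesis genes, 16 were lower, 1 was higher and 6 did not pass (camera adjusted p = 2.95e-04, and adjusted p = 0.768 with an estimated correlation). LSS fell from 1.24e+03 to 292 CPM (log2 fold change -2.09 ± 0.12 SE, edgeR adjusted p = 4.68e-06), and FDPS (-2.60 ± 0.16) and FDFT1 (-1.53 ± 0.13) fell in 5 of 5 donors. STARD4, which carries cholesterol and was named after its value was seen, rose by 0.32 ± 0.11, a call that ended without replicate 1 (adjusted p = 0.0897), 2 (0.0953), 3 (0.0545) or 5 (0.0886), with upper-quartile scaling (0.116) and without the donor block (0.136), in a range of 0.00595 to 0.136. Of 11 fatty acid synthesis genes, 9 fell and 2 did not pass (camera adjusted p = 6.58e-04, and adjusted p = 0.768 with an estimated correlation). The acetyl-CoA synthetase gene ACSS2 (-3.03 ± 0.19), the desaturase genes FADS1 (-2.28 ± 0.19), FADS2 (-1.78 ± 0.12) and SCD (-1.48 ± 0.17) and their regulator SREBF1 (-1.30 ± 0.10) fell. Of 9 adipogenic and lipid storage genes, 3 rose, 2 fell and 4 did not pass, with CD36 (2.19 ± 0.11) and PLIN2 (0.99 ± 0.14) higher and CEBPD (8.01-fold) lower. Its median (0.25) and camera's direction lay above 0 and its mean (-0.03) below (camera adjusted p = 0.896), and that direction turned down without replicate 4 (0.953) and without the replicate block (0.958).

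Stress genes moved in different directions. Of 12 heat shock genes, 9 rose, 1 fell and 2 did not pass (9 higher and 2 lower adjusted over the list alone, and also 2 lower with upper-quartile or library-size scaling, camera adjusted p = 0.00979, and adjusted p = 0.768 with an estimated correlation). HSPD1 (log2 fold change 1.54 ± 0.12 SE, edgeR adjusted p = 1.33e-05), HSP90AA1 (1.45 ± 0.16), HSPH1 (1.34 ± 0.15) and HSPA8 (1.28 ± 0.13) rose in 5 of 5 donors. The HSPA1A and HSPA1B genes of this list are near-identical, so their counts are uncertain. CRYAB, named after its value was seen, fell by 0.49 ± 0.18, a call that ended without replicate 1 (adjusted p = 0.111), 2 (0.145) or 3 (0.129) and without the donor block (0.288), in a range of 0.00459 to 0.288. Of 15 immediate early genes, 11 rose, 3 fell and 1 did not pass (camera adjusted p = 0.0177, and adjusted p = 0.768 with an estimated correlation or 0.146 without the replicate block). FOS (7.97-fold), FOSL1 (2.72 ± 0.11) and ATF3 (1.83 ± 0.18) rose, and EGR1 (-2.48 ± 0.24), JUNB (-0.97 ± 0.11) and EGR3 (-1.49 ± 0.45) fell. EGR3, named after its value was seen, was not past the threshold without replicate 1 (adjusted p = 0.0526), 2 (0.0680) or 3 (0.0645), in a range of 0.00302 to 0.0680. Of 14 cAMP response genes, 7 rose, 4 fell and 3 did not pass (camera adjusted p = 0.569), with DUSP1 (1.67 ± 0.10) and PDE4D (1.84 ± 0.19) higher and NR4A3 (-4.41 ± 0.25) lower.

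Of 15 endoplasmic reticulum chaperone and unfolded protein response genes, 1 rose, 4 fell and 10 did not pass (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.365). With upper-quartile scaling 8 were lower. DDIT3, a stress-induced transcription factor gene, rose by 2.35 ± 0.13 on the log2 scale (SE, edgeR adjusted p = 4.36e-06), while CRELD2 (-1.72 ± 0.20), HERPUD1 (-1.45 ± 0.19) and PDIA4 (-1.18 ± 0.22) fell. Of 20 ATF4 target and amino acid genes, 6 rose, 7 fell and 7 did not pass, with ATF4 (1.80 ± 0.14), SLC3A2 (2.37 ± 0.19) and VLDLR (1.54 ± 0.14) higher. Its camera direction was up (adjusted p = 0.681), turning down without replicate 1 (0.723), and its mean was -0.02. Of 17 NRF2 target genes, 9 rose, 3 fell (6 with upper-quartile scaling) and 5 did not pass (camera adjusted p = 0.329), with OSGIN1 (2.07 ± 0.14), SRXN1 (1.55 ± 0.13) and GCLM (0.70 ± 0.10) higher. PGD, an enzyme gene of the pentose phosphate pathway, fell by 1.38 ± 0.12 (adjusted p = 2.08e-05), a call that ended without the donor block (0.0664, in a range of 1.12e-22 to 0.0664). The metallothionein list also holds the zinc transporter gene SLC30A1. Of the list's 6 tested members, MT1F (2.14 ± 0.60) and MT1M (1.09 ± 0.40) rose and 4 did not pass (1 higher adjusted over the list alone, camera adjusted p = 0.319). Both calls ended without the donor block (adjusted p = 0.175 for MT1F, range 7.71e-04 to 0.175, and 0.0765 for MT1M, range 0.00776 to 0.0835). The call of MT1M also ended without replicate 2 (0.0533), 3 (0.0835) or 5 (0.0505) and with upper-quartile scaling (0.0517), and reads of these near-identical paralogs are hard to assign. The list members left out by the filter, MT1G (3 counts in control and 314 in LiCl libraries), MT1H (0 and 74) and MT1A (7 and 25), had more counts with LiCl.

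Of 24 lysosome and autophagy genes, 12 rose, 3 fell and 9 did not pass (9 higher and 6 lower with upper-quartile scaling, camera adjusted p = 0.125). The lysosomal channel gene MCOLN1 (log2 fold change 1.70 ± 0.10 SE, edgeR adjusted p = 5.61e-06), GLA (1.97 ± 0.14) and ATP6V0D1 (1.47 ± 0.14) rose, and the autophagy genes ULK1 (-3.22 ± 0.27), GABARAPL1 (-2.71 ± 0.24) and WIPI1 (-1.29 ± 0.14), named after their values were seen, fell. Of 21 glycolysis and hypoxia genes, 9 rose, 6 fell and 6 did not pass (camera adjusted p = 0.543), with the enolase genes ENO2 (1.67 ± 0.09) and ENO1 (1.15 ± 0.13) higher and ADM (-3.41 ± 0.26) and CA12 (-1.41 ± 0.11) lower. Of 15 circadian clock genes, 9 rose, 4 fell and 2 did not pass (10 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.117), with PER2 at 3.70 ± 0.38, BMAL1 at 1.72 ± 0.16 and CRY1 at 1.72 ± 0.18.

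Mitochondrially encoded mRNAs fell, 12 of 13 lower and 1 not past (camera adjusted p = 6.58e-04, and adjusted p = 0.768 with an estimated correlation). MT-CO1 fell from 1.10e+04 to 5.19e+03 CPM (log2 fold change -1.08 ± 0.12 SE, edgeR adjusted p = 7.34e-05), and MT-CYB (-1.16 ± 0.13), MT-CO3 (-0.99 ± 0.11) and MT-ATP8 (-0.98 ± 0.10) fell in 5 of 5 donors. MT-ND1, named after its value was seen, stood at -0.08 ± 0.14 (adjusted p = 0.637). Their share of all counts was 3.01 ± 0.34% in control and 1.72 ± 0.20% in LiCl libraries (SD, n = 5, exact paired p = 0.0625, lower in all 5 donors). Of 30 nuclear oxidative phosphorylation genes, 9 rose, 8 fell and 13 did not pass (8 and 8 adjusted over the list alone, camera adjusted p = 0.615), with CYC1 at 1.06 ± 0.10 and NDUFB5 at -1.36 ± 0.16. Of 30 cytosolic ribosomal protein genes, 3 rose, 4 fell and 23 did not pass. Upper-quartile scaling gave 2 higher and 10 lower, and library-size scaling 5 and 5. Adjusted over the list alone edgeR and limma-voom called 0, DESeq2 called 3 higher and 1 lower, and 5 were higher and 5 lower at an unadjusted p under 0.05 with edgeR. RPL19 (0.40 ± 0.12) rose and RPL10A fell by 0.45 ± 0.14, a call that ended without replicate 4 (adjusted p = 0.0629) or 5 (0.0562), in a range of 0.00170 to 0.0629. Camera's direction for ribosomal proteins was up (adjusted p = 0.988) with a mean of -0.01, and turned down without replicate 3 (0.432) and without the replicate block (0.993).

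**Figure D3:**
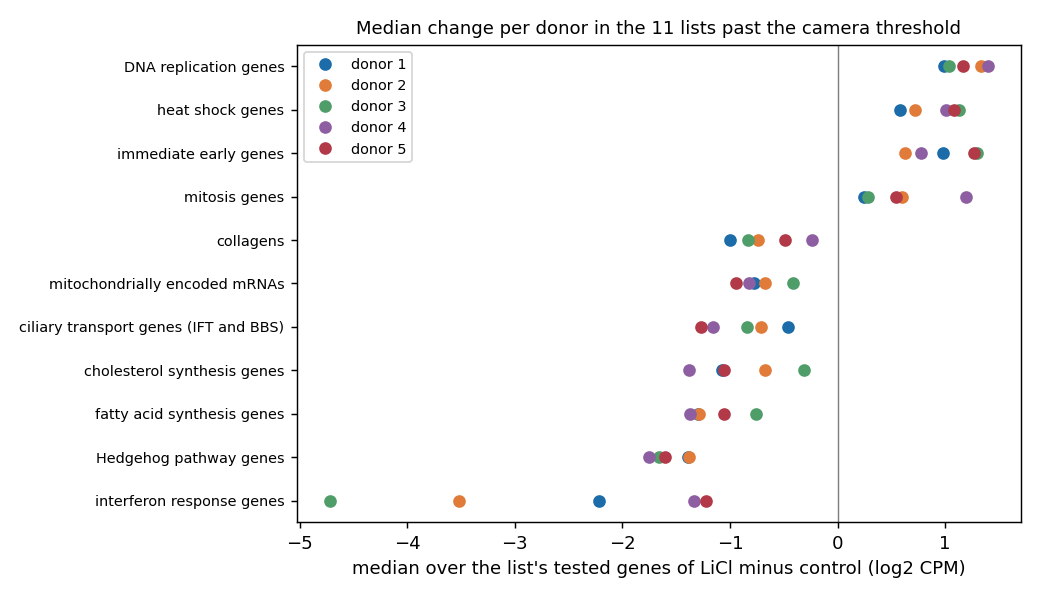
Points show, for each of the 5 donors, the median LiCl minus control difference in log2 CPM (x axis) over the tested members of the 11 lists past the camera threshold (y axis). The interferon list spreads from -4.72 to -1.23 between donors, and the DNA replication list from 0.99 to 1.39.

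Markers of other cell types were low or divided. Of the keratinocyte markers, the 2 tested rose, KRT10 by 1.40 ± 0.12 on the log2 scale (SE, edgeR adjusted p = 1.70e-05) and KRT14 from 2 to 228 counts (ratio 126, 95% counting interval 34.5 to 1048). KRT5, the partner of KRT14, had 0 counts in control and 1 in LiCl libraries. Of the endothelial markers 2 were tested and KDR rose by 2.03 ± 0.37 (adjusted p = 0.0632 without the donor block, in a range of 1.35e-08 to 0.0632). Of 8 pericyte and smooth muscle markers tested, CSPG4 (2.01 ± 0.24), RGS5 (0.85 ± 0.22) and MYH11 rose and MCAM (-1.49 ± 0.27) fell. The leukocyte marker CD68, which fibroblasts also express, stood at 0.44 ± 0.21 (adjusted p = 0.0889), and passed without replicate 3 (0.00367) and with DESeq2 (0.0416), in a range of 0.00367 to 0.443. Of the melanocyte markers only MITF was tested, and fell by 2.45 ± 0.23, while TYR had 0 counts in control and 126 in LiCl libraries. The 1 Schwann cell marker and the 1 adipocyte marker tested did not pass with edgeR, DESeq2 or limma-voom or at an unadjusted p under 0.05. Of 4 genes used to judge RNA quality, GAPDH rose by 0.46 ± 0.12, ACTB (0.00 ± 0.13) and MALAT1 (-0.04 ± 0.11) did not pass and NEAT1 fell by 0.52 ± 0.19 (adjusted p = 0.0370). The NEAT1 call ended without replicate 2 (0.0977), 3 (0.0895), 4 (0.102) or 5 (0.0558) and without the donor block (0.0627), in a range of 0.00761 to 0.102.

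Treatment separated the libraries more than donor did. Over genes, a median of 58.1% of the variance in log2 CPM lay between treatments, 24.2% between donors and 10.2% in the residual, and the leading principal component (58.3% of the variance) set the 5 LiCl libraries apart from the 5 control libraries. The correlation across genes of the LiCl response between donors was between 0.774 and 0.891 for the 10 pairs of donors, with a median of 0.819. Genes are not independent replicates. Of the 37 lists, 11 passed camera with its preset correlation of 0.01. With an estimated correlation camera called 0, 0 lists had an unadjusted p under 0.05, and the lowest unadjusted p was 0.0703, while fry called 26. Upper-quartile scaling moved the median log2 fold change of all genes from -0.04 to -0.13. Some list medians changed sign with the scaling. That of TGF-beta went from -0.01 to 0.01 with RLE or library size, that of ribosomal protein genes from 0.00 to 0.01, that of ATF4 from 0.00 to -0.09 with upper-quartile scaling, and that of nuclear oxidative phosphorylation from 0.08 to -0.02. The mean of the TGF-beta list (0.07) lay above 0 while camera's direction was down. With each library's trend with GC content and length removed in the same edgeR fit, 5533 genes were higher and 5036 lower, and the counts of some lists moved by over 1.5 times. Non-collagen matrix genes then had 7 higher and 15 lower, ribosomal protein genes 5 and 1, contractile genes 2 and 7 and endoplasmic reticulum genes 2 and 3. Circadian clock genes had 9 higher and 2 lower and adipogenic genes 3 and 1. The calls of STARD4 in the cholesterol list (15 lower) and CRYAB in the heat shock list (10 higher) ended. The medians of the ribosomal protein and TGF-beta lists turned from 0.00 to 0.04 and from -0.01 to 0.05.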

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

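The tests of the interferon list were chosen only after the result was seen, while those of the collagens and the mitochondrial mRNAs, and the search for libraries far from the others, were fixed before their results were known. A library was singled out where its gap to the nearest of the 5 libraries of its group took an unusually large share of the group's range. This was so in 19 of 534 groups (3.56%), and about 5% is what chance gives.

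Control replicate 3 had the lowest TMM factor of the controls, 0.929 against 1.00 for the nearest (share 0.729 of the range). In log2 CPM, control replicate 5 was lowest for ACTA2 (5.87, nearest 6.29, share 0.812) and SLC6A6 (6.20, nearest 6.71, share 0.835), and control replicate 4 was lowest for BMP2 (3.16, nearest 5.29, share 0.837), CA12 (6.68, nearest 8.16, share 0.733) and SDHB (4.87, nearest 5.21, share 0.747). Control replicate 4 was highest for COL5A1 (8.95, nearest 7.98, share 0.716) and BMAL1 (3.80, nearest 3.58, share 0.775). LiCl replicate 1 was lowest for AXIN2 (3.72, nearest 5.41, share 0.763), S100A4 (8.49, nearest 9.10, share 0.778) and UPF3B (4.89, nearest 5.46, share 0.774) and highest for ULK1 (3.58, nearest 2.46, share 0.735). LiCl replicate 5 was lowest for THBS1 (7.69, nearest 8.67, share 0.846) and highest for CDC6 (5.84, nearest 5.31, share 0.712) and SLC6A2 (3.92, nearest 1.05, share 0.753), and LiCl replicate 3 was lowest for ENO2 (6.05, nearest 6.50, share 0.785). CCL18, LINC02725 and SLC6A2 each had counts in a single control library, which gives a share of 1 for each.

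Of 21 collagen genes 13 fell, with a median log2 fold change of -0.48. Genes rich in GC fell more than others (median log2 fold change -0.30 in the 3901 richest in GC against 0.10 in the 3902 poorest), but with the trend of each library with GC content and length removed the collagen median was -0.43 with 10 genes lower, so this trend is not the whole of it. Across 3 other scalings the fewest collagens lower was 11, which argues only against the choice among these scalings as the cause. Their median log2 fold changes over all genes differ little (-0.04 with TMM, -0.02 with RLE, -0.13 with upper quartile, -0.02 with library size), so this was a narrow test. Each scaling is relative to the counts of the library, so a change in the total RNA of the cells was not tested. A response to LiCl may account for the fall, as a hypothesis, and what LiCl did to cell number or survival was not measured.

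Of 13 mitochondrial mRNAs 12 fell, with a median of -0.66. After removal of the GC and length trend the median was -0.73 with 12 still lower, which argues against this trend as the cause. Across 3 other scalings the fewest lower was 12, which argues only against the choice among these similar scalings. What lowered the mitochondrial transcripts with LiCl remains open. Whether the cells held fewer mitochondria, or made or kept less of this RNA, was not tested.

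Interferon response genes had very unequal control levels, from a mean of 2.14 log2 CPM in replicate 4 to 9.15 in replicate 3. A single donor with high control levels does not account for the fall, since in 5 of 5 donors the median difference was below -0.5, and without replicate 3 there were still 15 members lower, with 2 higher. PTPRC, CD3E, MS4A1 and LYZ, the highest at 0.0568 CPM in the control libraries, argue only against leukocytes that express them. Of the same marker list, CD68 (223 ± 117 CPM), CD74 (2.27 ± 2.99), CD14 (1.14 ± 0.53) and CSF1R (0.231 ± 0.127) stood above 0.0568 CPM in the control libraries. Their LiCl means were 276, 1.40, 1.38 and 0.490 CPM in the same order, and none passed the threshold with edgeR. The control levels of these markers therefore do not rule out leukocytes in the control cultures. A lower interferon response with LiCl may be biological, as a hypothesis formed and tested on the same data, and the unequal control levels remain unexplained.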

How the results depend on the processing

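The order of the libraries was the only alternative chosen after the data were seen. The counts of genes changed, higher, lower and changed at least 2-fold stayed within 1.5 times their values under each alternative run. Genes changed ran from 8614 (adjusted p under 0.01) to 11603 (under 0.10), with 9562 to 10394 on leaving out a donor, 9482 with no replicate block, 9577 with the stricter filter and 11352 with no filter. Of the 10641 genes, 9377 were called with no replicate block in the same direction. Of the calls, 48% were higher, and 43.1% with upper-quartile scaling.

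The 11 lists past the camera threshold became 0 with an estimated correlation and 26 with fry, which asks another question, and the same numbers, 0 and 26, with the LiCl libraries listed first. Other settings gave 9 (no replicate block) to 13 lists (without replicate 2, with 11 the lowest on leaving out a donor), and the adjusted p of the 11 lists ran from 3.35e-06 to 0.768 over the alternatives. The share of variance between treatments was 62.1% with the stricter filter, and 58.0% to 65.0% on leaving out a donor (65.0% without replicate 1). The cause of these shifts was not tested, except that the stricter filter removes genes of low count. The median correlation of the response between donors ran from 0.799 to 0.848.

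Of 258 genes followed, which include the tested genes whose fold changes are printed, 247 were past the threshold. In 3195 tests of these under the alternatives 3127 kept the call, 68 lost it, in 27 genes, and 0 turned direction. Leaving out the block gave 22 of the losses, and 19 calls were gained by genes not past before. Besides losses given with the genes, COL3A1 was not past with no filter (adjusted p = 0.050, range 9.35e-04 to 0.050) and NFAT5 was not with RLE (0.0517), no filter (0.0922), DESeq2 (0.0687) or no replicate block (0.191), from 0.00766 up. Without the block COL5A1, COL11A1, LTBP2, CXCL6, GLI2, THY1 and KRT34, whose fold changes are not given here, were not past either (0.0636 to 0.132). Calls were gained by RSAD2 and CMPK2 under further settings, among them DESeq2 (0.00158 and 0.00495) and limma-voom (0.0159 and 0.0293). The paired structure changed no count of genes by over 1.5 times (9482 with no replicate block). LEF1, with 8 counts in control and 217 in LiCl libraries, was left out by the filter and tested only with no filter.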

Other observations

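The families described here were chosen after their values were seen, 10 of 50 families looked at, and the test of nonsense-mediated decay was written before its result was seen. Host genes of small nucleolar RNAs rose in 18 of 27 cases, fell in 3 and did not pass in 6 (median log2 fold change 1.08), with SNHG15 at 3.39 ± 0.18 and SNHG1 at 3.34 ± 0.21 (SE, n = 5) higher and SNHG18 at -2.11 ± 0.21 lower. All 10 tested UTP genes of the small subunit processome, which builds ribosomes, rose (median 0.98), or 9 of them with upper-quartile scaling, with UTP4 at 1.64 ± 0.09 and UTP20 at 1.27 ± 0.12. Vacuolar ATPase genes, which acidify lysosomes, rose in 14 of 18 cases, fell in 3 and did not pass in 1 (median 1.22), with ATP6V1D at 1.71 ± 0.15. Of 15 tubulin genes, pseudogenes left out, 11 rose, TUBG2 fell and 3 did not pass (median 1.39), with TUBA1C at 2.07 ± 0.11 and TUBB4B at 2.05 ± 0.13, though some reads are shared between these paralogs. Of 20 nucleoporin genes with NUP symbols 15 rose (14 with upper-quartile scaling), NUP37 fell (-1.41 ± 0.21) and 4 did not pass (median 0.68), with NUP205 at 1.34 ± 0.12. Of 10 keratin genes 8 rose and 2 did not pass (median 2.14), with KRT16 at 7.25 ± 0.58 (from a control mean of 0.0258 CPM) and KRT17 at 2.28 ± 0.55.

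Guanylate-binding protein genes, which interferon induces, fell in 5 of 5 cases (median -3.33, GBP2 at -3.33 ± 0.43). Of 16 peroxin genes, which build peroxisomes, 11 fell, 3 rose and 2 did not pass (median -1.01), with PEX11G at -3.43 ± 0.31. All 4 YPEL genes tested fell (median -2.85, YPEL3 at -3.08 ± 0.26), too few for camera. Of 29 HOX genes, which mark position along the body, 17 fell, 6 rose and 6 did not pass (median -0.63, camera adjusted p = 0.208, and 0.575 with an estimated correlation), with HOXD9 at -2.71 ± 0.31 and HOXB5 at 4.57 ± 0.33. Camera's adjusted p over the families was 2.68e-04 for the UTP and vacuolar ATPase genes, 3.82e-04 for tubulins and nucleoporins, 4.62e-04 for keratins, 6.20e-04 for the small nucleolar RNA host genes, 0.00814 for guanylate-binding proteins and 0.0142 for peroxins. With an estimated correlation the adjusted p was 0.191 to 0.323 for these 8 families. No median of the 10 families changed sign under RLE, upper-quartile or library-size scaling. Since the families were picked for their change, these p-values are too small.

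Transcripts of small nucleolar RNA host genes are known to be degraded by nonsense-mediated decay, and less nonsense-mediated decay with LiCl is a candidate explanation for their rise. Decay factor genes are held down by the same decay, so they should rise with it. Of 7 decay factor genes fixed for the test, 6 rose (median log2 fold change 0.70), among them UPF3B at 1.38 ± 0.11 and UPF1 at 1.05 ± 0.10, while SMG6 stood at -0.15 ± 0.09 (edgeR adjusted p = 0.197, and 0.0384 with upper-quartile scaling, in a range of 0.0384 to 0.416). With 5106 of 15835 genes higher, such a rise could also come from higher transcription, which these data do not separate.

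In 100 splits of the 10 libraries into 5 and 5, 1 split, the real one, gave as many genes changed (10641), higher (5106), lower (5535) or changed at least 2-fold (5488), and the highest count of the other splits was 0 in each case. Among the 10 other splits drawn that part all 5 pairs the highest was also 0. Only 16 splits part all 5 pairs, too few for a share under 0.05 (the smallest is 0.0625). The other splits also leave the treatment difference in the residual, which lowers their counts by construction. For the number of lists past the camera threshold, 68 of 100 splits gave 11 or more, the highest of the others 17, and 15 among those that part all 5 pairs. Each of the other splits puts unequal numbers of LiCl libraries on the 2 sides and so holds part of the treatment difference. None of them shows what chance gives with no treatment, and for the lists, too, the paired splits are too few.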
